A study of Mus musculus with 2 samples.

How the data were processed

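The series holds droplet single-cell RNA sequencing of leukocytes from YUMM1.7 melanomas, with 1 pooled library per genotype and 6 mice in each pool. Per the labels, 60000 CD45+ DAPI− cells per genotype were pooled, 5000 were targeted on a Chromium system with 3' v3 chemistry, and libraries were read on a NextSeq. Per the file headers, the matrices come from Cell Ranger 3.0.1, and per the labels the build is mm10. The deposited matrices hold raw UMI counts per gene and barcode as the authors made them, without scaling. A deposited table made by the authors with Seurat 3.0.2, per the submitters' processing notes, gives for each annotated cell its library, its cell type name, its UMI count and the percent of its UMIs from mitochondrial genes. Per the file headers, its column names are those of an integrated assay clustered at resolution 0.8. How cells were named, whether reads were counted by strand, and any doublet removal are not given in the sources used here. On the matrices, every one of the 702 barcodes outside the annotation had at least 10% mitochondrial UMIs, at most 200 genes or at least 6000 genes.

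Both matrices list 27998 genes, of which 19099 had at least 1 UMI, and 27645 IDs (98.7%) were found in the GENCODE M21 annotation of mm10, the source of every position given. Genes are identified by Ensembl ID, and 56 symbols belong to more than 1 gene. Reads that fall equally on near-identical genes can be lost or split, so values of the Ly6, Gbp, Ifit, Hspa1, granzyme and Pydc3 families carry that uncertainty, as does the antisense gene Gm26740.

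The authors' 26 names were used as given and, being more than 12, also merged by lineage. The monocyte/macrophage class joins Monocytes 1 to 3, both Mø clusters and the skin resident Mø, a label of few cells placed here by its name alone, since it scored low on every fixed marker list. The MDSC class joins the M-MDSC and G-MDSC names, the DC class cDC 1, cDC 2, migratory DCs and pDCs, the T class CD4+, CD8+ and NKT cells, and the NK class both NK clusters. B cells and mast cells with basophils stood alone. Cycling CD8+ T cells, a mixed cluster, stromal cells and a cycling myeloid cluster were kept apart. The authors named the last one Monocytic DCs, and it scored highest on proliferation markers and next on macrophage markers. Classes with at least 100 cells per library entered the comparison of expression: 1734 and 1557 monocytes and macrophages, 852 and 731 DCs, 726 and 797 MDSCs, 430 and 910 T cells and 247 and 744 NK cells (APOE2 and APOE4). Median UMIs per cell were 8010 and 7046, 10164 and 8905, 1666 and 1682, 3474 and 3510, and 4683 and 3857 in the same order.

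Shares are percents of annotated cells with exact Clopper-Pearson 95% intervals, and ratios of shares (APOE4/APOE2) carry the interval of the log ratio of binomial counts. A count of 0 cells allows a share of up to 0.0643% in APOE2 and 0.0557% in APOE4 (3 counts). Expression was the sum of UMIs per class and library in CPM of the class total, and its ratio carries the exact conditional binomial 95% interval of 2 counts. For single folds over a class, a gene with 0 UMIs in a library was set to a floor of 3 counts in that library and its fold written as a lower bound. In list medians a small constant was added to both counts where either was 0. In means over labels it was added to every count, so equal-label folds of genes with few UMIs in a library, such as Gm20186, Erdr1 and Asns, lean on it. Cells are not replicates, so no p-value, standard error or number of changed genes was computed.

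The gene lists were fixed before the data were examined, as were the cell type markers, the rule for naming genes and the alternatives, except where a choice is said to be later. The 25 lists cover type I interferon and interferon gamma responses, MHC class I, MHC class II, cytotoxic effectors, T cell exhaustion, naive and memory T cells, T cell activation, alternatively activated myeloid genes, inflammatory cytokines, LXR targets, cholesterol synthesis, APOE receptors, lysosome, hypoxia and glycolysis, oxidative phosphorylation, proliferation, complement, dissociation stress, the unfolded protein response, ribosomal proteins, mitochondrial genes, sex-linked genes, granule contents and neutrophil trafficking. Each was summarised by the median log2 ratio of members with at least 20 UMIs in the class, with an order-statistic 95% interval, and by its percentile among 10000 random lists of the same size matched on expression in 20 bins (seed 0). The percentile describes these libraries only and was given for lists with at least 5 members. All 125 combinations of list and class were computed.

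Genes were named within the 4 classes with the most cells, among genes with at least 100 UMIs in the class and a CPM of at least 10% of that in the gene's highest class, leaving out ribosomal, mitochondrial, sex-linked, haemoglobin and receptor segment genes. The 6 highest and 6 lowest ratios were taken, ranked by the bound of the interval nearest to 1. Up to 4 members of each list with the highest CPM were taken as examples. NK cells had lists and examples only. Single values of some list members are not reported.

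Alternatives covered which cells count, denominators, own clusters, all barcodes, 3 other scalings (TMM, median of ratios, totals without ribosomal and mitochondrial genes), the weight of cells and labels, cells thinned to 1500 UMIs, doublet scores, filters on low counts, mean in place of median, and the ranking of named genes. Thinning left out cells with fewer than 1500 UMIs. Added after seeing the data were equal label weight for lists, cycling clusters put back in their lineages, lists without 5 genes near 0 in a library, clusters without the 2748 genes at a log2 ratio of 1 or more either way or in the interferon and alternatively activated lists, depth with other cell filters, and the removal of the 5% of cells with the highest Scrublet scores for folds, lists and depth. Own clusters used 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolutions of 1, 0.5 and 2, named by the fixed markers. Doublets were not removed for the main values. Scrublet called 0 and 3 cells at an expected 4%, too few to act on.

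The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM factors. The computation was tested on simulated Poisson counts drawn from the real class means and totals with 200 changed genes. The intervals assume such counts, so this tests the code and not the spread of real cells or mice. Intervals held the true ratio for 94.8% of unchanged genes in the monocyte/macrophage class, 96.0% in DCs, 96.4% in MDSCs, 96.1% in T cells and 95.8% in NK cells. For changed genes they held it in 93%, 95%, 91%, 94.5% and 96%, in the same order. They excluded 1 for 91%, 90.5%, 78.5%, 82% and 77.5% of changed genes. Of 40 lists of unchanged genes per class, 1, 4, 1, 1 and 0 had percentiles outside the central 95%. Doubled genes came back at a median of 1.97, 2.08, 2.01, 2.01 and 1.95 in the same order, and halved genes at 0.492, 0.498, 0.480, 0.505 and 0.499. The interval of share ratios held the true value in 95.0% of 4000 simulations. Tumour-derived transcripts, shares of cells with a UMI of a marker and phase calls were not analysed here.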

Results

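Single-cell transcriptomes were collected from CD45+ DAPI− leukocytes of YUMM1.7 tumours, a mouse melanoma line grown under the flank skin of mice that carry human APOE2 or human APOE4 in place of the mouse gene. APOE is a lipid carrier made by macrophages among others, and its variants differ in how they bind receptors. Tumours were taken on day 19 after injection of 100000 cells. Each genotype gave 1 library, a pool of 10000 sorted cells from each of 6 mice. The deposited matrices hold 5063 barcodes and 41207514 UMIs (unique molecules counted) for APOE2, and 5689 barcodes and 37349222 UMIs for APOE4. The authors annotated 4665 and 5385 of these cells with 26 cell type names. Annotated cells had a median of 7160 UMIs and 2376 genes in the APOE2 library and 5560 UMIs and 2059 genes in the APOE4 library. At an equal 1500 UMIs per cell the medians were 831 and 849 genes, with 348 and 340 cells of lower depth left out. With 1 library per genotype there are no replicates, so every comparison is between these libraries. The 95% interval of a share or of a gene's ratio covers counting error only. That of a list median covers the spread over the list's members, and neither kind covers differences between libraries of 1 genotype.

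The first comparison asked which leukocytes filled the tumours of each genotype. Lymphocytes took a larger part of the APOE4 library and myeloid cells a larger part of the APOE2 library. NK cells, which kill without prior priming, were 5.29% of APOE2 cells and 13.8% of APOE4 cells, a ratio of 2.61 [2.27, 2.997]. CD8+ T cells, which kill cells that present a recognised peptide, were 2.42% and 8.86%, a ratio of 3.66 [2.99, 4.47]. The 3 macrophage labels together went the other way, at 19.8% and 7.69%, a ratio of 0.387 [0.347, 0.432]. The smallest of them, skin resident Mø with 47 and 8 cells, did not score as macrophages on the fixed markers, and the larger Mø clusters 1 and 2 had ratios of 0.441 and 0.350.

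Lymphoid cells as a whole were 16.4% and 33.2% of the libraries, a ratio of 2.03 [1.88, 2.19]. T cells outside cycling clusters were 9.22% and 16.9%, a ratio of 1.83 [1.65, 2.04]. Most of that gap lay in CD8+ T cells, because CD4+ T cells held 5.08% and 5.63%, a ratio of 1.11 [0.939, 1.31]. The CD4+ label scored highest on regulatory T cell markers and next on those of gamma delta T cells, so it cannot be taken as CD4+ cells alone. Own clusters that scored highest on gamma delta markers had only 2 of them detected, too few for the naming rule. The denominator mattered here: T cells were a slightly smaller part of lymphoid cells in the APOE4 library, 50.8% against 56.3%, a ratio of 0.903 [0.836, 0.976]. Of lymphoid cells, CD4+ T cells had a ratio of 0.546 [0.471, 0.632], CD8+ T cells 1.80 [1.49, 2.17] and NK cells 1.29 [1.14, 1.44]. B cells, at 0.772% and 1.15%, had an interval that included 1, and their gap closed when only cells under 5% mitochondrial UMIs were kept (log2 ratio −0.05).

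Among myeloid cells, the monocyte/macrophage class was 37.2% and 28.9% of all cells, a ratio of 0.778 [0.735, 0.823], but its share of the myeloid cells was alike, with a ratio of 0.999 [0.951, 1.05]. Inside that class macrophage names were 25.7% of myeloid cells in APOE2 and 12.8% in APOE4. The gain in monocyte names lay in Monocytes 2 (5.71% and 16.2% of myeloid cells) and Monocytes 3 (4.69% and 7.19%). Monocytes 1 was level, with a ratio of 0.987 [0.867, 1.12]. Monocytes 2 is led in part by genes that differ between the libraries, such as Cxcl9 and Fam26f. The size of Monocytes 2 is thus not independent of them. Monocytes 1 and 2 scored slightly higher on macrophage than on monocyte markers. Dendritic cells (DCs), which present antigen to T cells, were 18.3% and 13.6% of all cells, a ratio of 0.743, but of myeloid cells the difference was within counting error, 0.955 [0.875, 1.04]. This class leaves out the cycling cells that the authors named Monocytic DCs. Those had a ratio of 0.573 [0.462, 0.711] of myeloid cells. The types within the DC class parted. The cDC1 (0.547), cDC2 (0.611) and migratory (0.675) labels had lower shares of all cells in the APOE4 library, although of myeloid cells the migratory label had 0.867 [0.702, 1.07], and the pDC label, plasmacytoid cells known for making type I interferon, had a higher one, 3.81% against 2.38%. The cells the authors named MDSC (myeloid-derived suppressor cells, all 4 labels of which scored highest on neutrophil markers) were 15.6% and 14.8% of all cells, a difference within counting error, but of myeloid cells they had a ratio of 1.22 [1.12, 1.33]. Their labels did not all keep this balance, but no share ratios are given for them, since interferon genes that differ between the libraries lead M-MDSC 2. Mast cells and basophils were 1.29% and 0.650%.

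Since many genes that shape clusters differed between the libraries, the annotated cells were also clustered without 2748 such genes, a choice made after seeing the data. These clusters were still named by the full marker lists, which hold genes that differ, such as Ly6c2 and Mrc1. Macrophages then had a share ratio of 0.373 [0.338, 0.411] and monocytes 1.67 [1.52, 1.84]. The ratio was 3.29 [2.76, 3.92] for CD8 T cells, 2.53 [2.21, 2.89] for NK cells, 0.562 [0.485, 0.651] for cDC2 and 1.69 [1.33, 2.15] for pDCs. A fixed number of cells was sorted from each mouse, so the shares carry no information on how many leukocytes a tumour held.

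**Figure D1:**
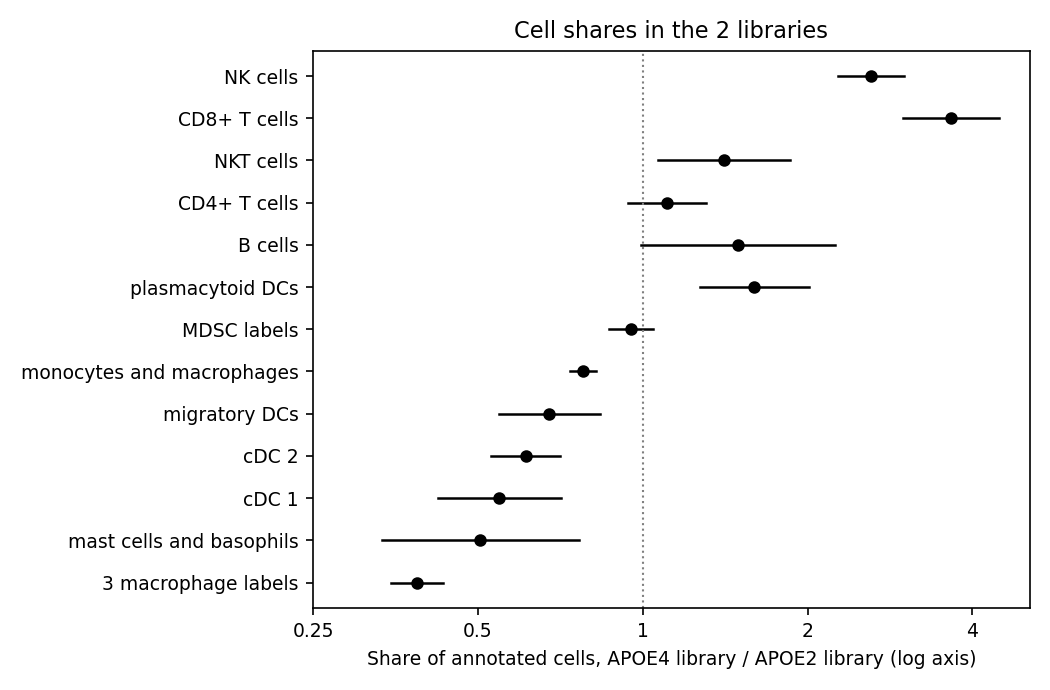
Ratio of the share of annotated cells of 13 selected classes and labels, APOE4 library over APOE2 library, on a log axis, where points are ratios, bars are 95% intervals for counting error and the dotted line marks equal shares. CD8+ T cells (3.66) and NK cells (2.61) lie farthest to the right among the groups drawn and the 3 macrophage labels together (0.387) farthest to the left, and some single labels that are not drawn lie outside this range.

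Expression was then compared within each class to ask which programmes differed in cells of the same kind. Genes induced by interferons were higher in the APOE4 library in all 5 classes with at least 100 cells per library. The type I interferon list, antiviral genes such as Isg15 and Irf7, had a median log2 ratio of 2.21 [1.76, 2.44] in MDSCs, 1.79 [1.51, 1.90] in the monocyte/macrophage class, 1.54 [1.32, 1.70] in DCs, 0.93 [0.83, 1.19] in T cells and 0.69 [0.47, 0.80] in NK cells. No measured member was lower in any of these classes, and each median was at percentile 100 among 10000 random lists matched on expression.

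The interferon gamma list, which holds guanylate-binding proteins and the CXCR3 chemokines that draw T cells, was higher by 2.12 [1.61, 3.0] in MDSCs, 1.74 [1.05, 1.99] in the monocyte/macrophage class and 0.95 [0.49, 1.32] in DCs. It was 0.28 [0.07, 0.53] in T cells and 0.22 [−0.01, 0.48] in NK cells. When the labels of the MDSC class were given equal weight, its medians were 1.28 for type I and 1.46 for interferon gamma genes. In the monocyte/macrophage class, Isg15 stood at 262 and 1064 CPM (UMIs scaled to the class total), Irf7 at 179 and 714, Ly6a at 341 and 1573, and the chemokine Cxcl10 at 256 and 1201. Over single labels with enough cells, the type I list was higher in 22 of 22, from 0.39 in Monocytes 2 to 2.46 in pDCs, and the interferon gamma list in 22 of 22, from 0.16 to 1.90.

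The machinery that loads peptide onto MHC class I, an interferon-responsive set that shares 5 genes with the gamma list, was higher in the same 5 classes, with medians of 1.62 in MDSCs, 1.09 in the monocyte/macrophage class, 0.63 in DCs, 0.26 in T cells and 0.22 in NK cells. All 16 members were higher in each of the 3 myeloid classes, with H2-K1 1.83-fold and B2m 1.67-fold higher in the monocyte/macrophage class. MHC class II genes, used to present to CD4+ T cells, went both ways. Their median was 0.23 [−0.02, 0.46] in the monocyte/macrophage class, with 11 of 15 members higher, and within labels 0.47 in Mø cluster 1, 0.29 in Mø cluster 2, 0.23 in Monocytes 1, −0.12 in Monocytes 2 and −0.22 in Monocytes 3. It was −0.31 in DCs, with 12 of 15 members lower and Cd74 at a ratio of 0.713. Equal weight per DC label brought the latter close to 0 (−0.011), a setting added after seeing the data. In the other classes, where these genes are weakly read, it was −0.81 in MDSCs (0.33 without the cells of highest doublet score), −0.82 in T cells and −0.29 in NK cells (0.24 with own clusters as classes).

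**Figure D2:**
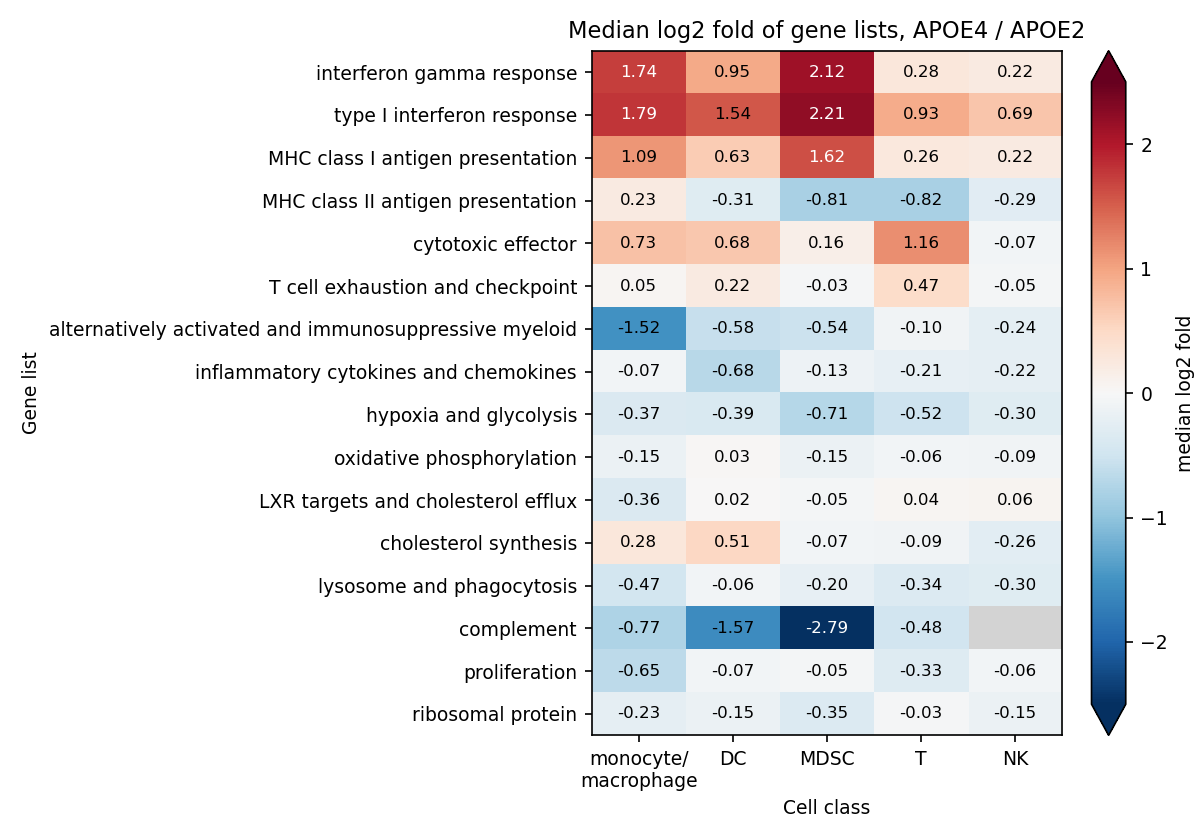
Median log2 ratio APOE4/APOE2 of 16 of the fixed gene lists in each of the 5 classes, on a colour scale centred at 0, with grey where fewer than 5 members were measured. The type I interferon list is positive throughout, from 0.69 in NK cells to 2.21 in MDSCs, and hypoxia and glycolysis genes are negative throughout, from −0.30 in NK cells to −0.71 in MDSCs.

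Monocytes and macrophages of the APOE4 library had more Ly6c2 and Ly6i and less Arg1 and Mrc1. Ly6c2, a surface antigen of newly arrived monocytes, was at 274 and 1755 CPM, 6.40-fold higher [6.20, 6.62], and its family member Ly6i was 9.23-fold higher [8.54, 9.98]. Fam26f, which interferon gamma induces, was 5.86-fold higher [5.28, 6.51], and the guanylate-binding protein Gbp2b 7.30-fold [5.05, 10.9]. The list of alternatively activated and immunosuppressive genes had a median of −1.52 [−1.81, 0.14], with 16 members lower and 6 higher and an interval that included 0. Arginase 1 (Arg1), which depletes arginine needed by T cells, was at 918 and 275 CPM, and the mannose receptor Mrc1 at 782 and 223.

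The class differs in make-up: macrophage names form most of it in APOE2 and monocyte names in APOE4. With equal weight per label, Ly6i was 4.53-fold, Gbp2b 4.55-fold and Ly6c2 4.16-fold higher, though Gbp2b was lower in 1 of the 2 labels where it was measured. Pydc3, of a family that regulates inflammasomes, was 39.8-fold higher [24.6, 68.8], or 34.5-fold with equal label weight. The coding gene 1700112E06Rik was 15.2-fold higher [8.24, 31.3], or 23.6-fold with equal label weight.

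On the lower side, the eosinophil attractant Ccl24 was 10.8-fold lower [7.03, 17.6]. Suprabasin (Sbsn), best known from skin epithelium, was 23.6-fold lower [9.91, 73.8], Mid1, a ubiquitin ligase, 28.3-fold [12.8, 77.8] and Erdr1 59.3-fold [20.05, 290], or 31.9-fold with equal label weight. In cells thinned to 1500 UMIs the log2 fold of Mid1 in monocyte/macrophage cells was −3.34, and with own clusters the log2 fold of Sbsn in monocyte/macrophage cells was −3.85. The metallothionein Mt3 was 14.3-fold lower [8.66, 25.3], but it is a leading gene of the skin resident Mø label alone, and the gap ended when own clusters, which leave that label unnamed, formed the class (log2 ratio 0.11). Gm26740, an antisense RNA gene annotated on chromosome 10 from 22187013 to 22302835 (mm10), had 797 UMIs in APOE2 and 0 in APOE4, at least 201-fold lower against a floor of 3 counts. Complement genes had a median of −0.77 [−0.89, 1.82], an interval that included 0. C1qa was at 2961 and 1765 CPM over the class and had ratios of 0.956 and 0.848 in Mø clusters 1 and 2 and of 0.483, 0.397 and 0.142 in Monocytes 1, 2 and 3. Lysosomal and phagocytic genes were at −0.47 [−0.89, −0.06], with 17 of 23 members lower, Ctsb at a ratio of 0.647 and Ctss at 1.37, and at −0.07 to −0.32 within single labels.

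Lipid genes were examined because APOE carries cholesterol. The list of LXR targets and cholesterol efflux genes holds other lipid genes beside exporters of cholesterol, so it is no measure of efflux alone. It had a median of −0.36 [−0.80, 0.24] in the monocyte/macrophage class. There 11 members were lower, including Pltp (0.573) and Plin2 (0.697), and 8 higher, including Npc2 (1.48). Its medians were near 0 in DCs (0.02), MDSCs (−0.05), T cells (0.04) and NK cells (0.06). Cholesterol synthesis genes were higher in DCs, 0.51 [0.34, 0.76] with 17 of 18 members, and in the monocyte/macrophage class, 0.28 [0.15, 0.49] with 15 of 18, and not separable from 0 in MDSCs (−0.07), T cells (−0.09) and NK cells (−0.26). In DCs Fdps was 2.06-fold higher. Within cDC1, whose task is to present antigen to CD8+ T cells, the synthesis list reached 0.96 with 17 of 17 members higher. Known APOE receptors had medians of −0.13, −0.02, −0.48 and −0.16 in the monocyte/macrophage, DC, MDSC and T classes. Within single labels their median was above 0 in 8 of 11, from −0.42 in Monocytes 1 to 0.44 in the mixed cluster. Of these receptors, Trem2 (0.464) and Lrp1 (0.705) were lower in the monocyte/macrophage class, which holds fewer macrophage names in APOE4. Only 1 member was measured in NK cells (0.12).

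DCs of the APOE4 library held fewer transcripts of the fixed list of inflammatory cytokines and chemokines, and less Ccl17 and Cd207. The chemokine Ccl17, which attracts CCR4-bearing T cells, was at 333 and 46.4 CPM, 7.17-fold lower [6.40, 8.06]. Langerin (Cd207) was at 36.0 and 1.68 CPM, 21.4-fold lower [12.1, 41.8], and the ribonuclease Ear2 9.82-fold lower [6.80, 14.7]. The equal-weight mean over DC labels put Ccl17 further apart, at a log2 ratio of −3.78. For Cd207 it was −5.50, but this value rests on the constant added to counts. Cd207 had no UMIs in migratory DCs and cDC2 of the APOE4 library. Inflammatory cytokines and chemokines had a median of −0.68 [−1.37, −0.38] with 19 of 23 members lower, and Cxcl2 at a ratio of 0.170. The alternatively activated list was at −0.58 [−2.57, 0.09], with Mgl2 at 675 and 114 CPM.

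Among the genes higher in DCs of APOE4, Ly6c2 was 5.86-fold higher [5.53, 6.22] and the interferon-induced GTPase Iigp1 7.03-fold [5.65, 8.83]. The VEGF receptor Kdr was at 8.16 and 67.1 CPM, 8.22-fold higher [6.41, 10.7]. Asparagine synthetase (Asns) was 18.8-fold higher [8.82, 48.0], or 28.8-fold with equal label weight, and the peptide hormone secretin (Sct) 7.77-fold [5.57, 11.1]. Pydc3 was 36.4-fold higher [13.8, 136]. Erdr1 was 41.6-fold lower [16.0, 154] and Mid1 24.7-fold lower [10.4, 77.2]. Gm26740 had 468 and 0 UMIs, at least 124-fold lower. The pDC label made up 13.03% of the class in APOE2 and 28.0% in APOE4.

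MDSCs of the APOE4 library had more transcripts of interferon-induced genes and fewer of hypoxia and glycolysis genes. The class also differed in make-up by label, since M-MDSC 2, a label led by interferon genes such as Rsad2 and Ifit1, was 4.96% of it in APOE2 and 23.8% in APOE4. Because such genes differ between the libraries, the size of this label is not independent of the interferon result. Within labels the type I median was 1.84 in M-MDSC 1, 1.13 in G-MDSC 1 and 0.58 in M-MDSC 2. Over the class, the guanylate-binding protein Gbp2 was at 39.9 and 987 CPM, 24.8-fold higher [19.1, 32.8], and Gbp5 21.5-fold [10.2, 54.2]. Cxcl10 was 16.1-fold higher [12.8, 20.3], the GTPase Ifi47 12.4-fold [9.04, 17.5], and the antiviral genes Ifit2 and Ifit3 12.1-fold [8.60, 17.6] and 11.0-fold [8.88, 13.7]. Equal weight per label lowered these folds, to a log2 ratio of 3.22 for Gbp2, 2.40 for Cxcl10, 2.57 for Ifi47 and 2.77 for Ifit3, and left Gbp5 8.02-fold higher.

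Glutathione reductase (Gsr), which keeps cells supplied with reduced glutathione, was at 1222 and 75.5 CPM in MDSCs, 16.2-fold lower [13.4, 19.6]. The heat shock genes Hspa1b and Hspa1a, near-identical copies that can share reads, were 17.3-fold [11.5, 27.1] and 12.4-fold lower [8.29, 19.3]. In cells thinned to 1500 UMIs, the log2 fold of Hspa1b in MDSC cells was −2.98 and the log2 fold of Hspa1a in MDSC cells −2.44. Thinning left out 273 and 259 shallower MDSCs, so the set of cells differs too. Both genes had enough UMIs in only 1 label of the class. The neutrophil attractant Cxcl3 was at 3100 and 522 CPM, 5.94-fold lower [5.52, 6.41]. Gm26740 had 375 and 0 UMIs, at least 136-fold lower, and the long non-coding RNA Gm20186 was 43.1-fold lower [16.5, 160]. Granule contents (−0.13) and trafficking genes (0.08) had medians near 0, with S100a9 at a ratio of 0.861. The granule list's mean was positive (0.54).

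Genes of low oxygen and glycolysis were lower in the APOE4 library in all 5 classes. Their median was −0.71 [−0.98, −0.47] in MDSCs, −0.52 [−0.76, −0.27] in T cells, −0.39 [−0.50, −0.22] in DCs, −0.37 [−0.59, −0.16] in the monocyte/macrophage class and −0.30 [−0.56, −0.02] in NK cells. Over single labels the median was lowest in M-MDSC 2 (−1.26), which was 4.96% of the MDSC class in APOE2 and 23.8% in APOE4. Hilpda, which blocks lipid breakdown under low oxygen, was at 1108 and 374 CPM in MDSCs, and lactate dehydrogenase Ldha had ratios of 0.506 in MDSCs, 0.729 in T cells and 0.696 in NK cells. Proliferation genes were lower in the monocyte/macrophage class, −0.65 [−0.95, −0.24] with 22 of 23 members.

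T cells of the APOE4 library carried more effector transcripts. Interferon gamma itself (Ifng) was at 46.3 and 303 CPM, 6.55-fold higher [5.20, 8.35]. The cytotoxic list was higher by 1.16 [0.63, 1.43] with 15 of 18 members, among them Ccl5 at 2588 and 6048 CPM, Nkg7 at 790 and 1995 and granzyme B (Gzmb) at 904 and 1692. Checkpoint and exhaustion genes were higher by 0.47 [0.14, 0.83], with 13 of 15 members. This was so in the CD8+ label (0.47, 13 of 14 higher) but not in the CD4+ label (−0.18, 4 higher and 7 lower) or in NKT cells (−0.16, 3 higher and 8 lower). Over the class Pdcd1, which encodes PD-1, was 1.73-fold higher, while Ctla4 (0.630) and Tnfrsf9 (0.560) were lower.

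The APOE4 T class holds more CD8+ cells, 52.4% against 26.3%, and Cd8a and Cd8b1 were 5.47-fold [4.66, 6.46] and 3.89-fold higher [3.42, 4.44]. With equal weight per label the log2 ratio of Ifng was 1.89 and that of Cd8a 1.66. Inside the CD8+ label the cytotoxic list stood at 1.01 with 16 of 18 members higher, and inside the CD4+ label at 1.47 with 15 of 16. In NKT cells it was only 0.13, with 9 members higher and 5 lower, at percentile 91.7 of the random lists. Transcripts of CD8 itself were also higher in the CD4+ label, Cd8a with 5 and 36 UMIs and Cd8b1 with 5 and 62, and the cytotoxic list was higher in some cells that are not killers, such as cDC2 (1.41) and Mø cluster 2 (1.27). Over single labels of all kinds its median was above 0 in 16 of 21, from −0.20 in NK cluster 2 to 4.32 in B cells. Free RNA was not tested for this list. Naive and memory genes (−0.30) and activation genes (−0.39) had lower medians, with Tnfrsf4 at a ratio of 0.495 and Il7r at 0.739, and neither interval excluded 0. The naive and memory median was lower in the CD8+ label alone (−0.42), against 0.09 in CD4+ and 0.14 in NKT cells, and was 0.02 over the class with own clusters as classes. Own clusters named T may include cells of the mixed cluster.

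Enkephalin precursor (Penk) was 6.90-fold lower [5.34, 8.99] in T cells, the myeloid growth factor gene Csf2 6.94-fold [4.54, 10.9], the tetraspanin Cd81 3.90-fold [3.14, 4.87] and the growth factor amphiregulin (Areg) 3.26-fold lower [2.92, 3.63]. Equal label weight moved these to log2 ratios of −3.66, −2.19, −1.28 and −0.97, and Csf2 and Areg were each higher in 1 label. Pydc3 was 6.87-fold higher [4.74, 10.3], its family member BC094916 3.57-fold [2.75, 4.70] and the unnamed gene Gm29243 4.80-fold [2.87, 8.60]. Gm26740 had 489 and 0 UMIs, at least 342-fold lower, and Gm20186 144 and 2 UMIs, 151-fold lower [41.0, 1258], or 80.5-fold with equal label weight.

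NK cells were more numerous in the APOE4 library and differed in which granzymes they expressed. Their cytotoxic list was near 0 in the median, −0.07 with 9 members higher and 11 lower, because members parted, and its mean was −0.80. It was 0.21 in NK cluster 1 and −0.20 in NK cluster 2. Granzyme A (Gzma) was at 2472 and 4368 CPM, 1.77-fold higher [1.70, 1.84], and granzyme C (Gzmc) at 3947 and 194 CPM, 20.4-fold lower [18.7, 22.2]. Naive and memory genes were higher by 0.55 [0.19, 0.76] with 10 of 11 members, including Cd27 (1.46).

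**Figure D3:**
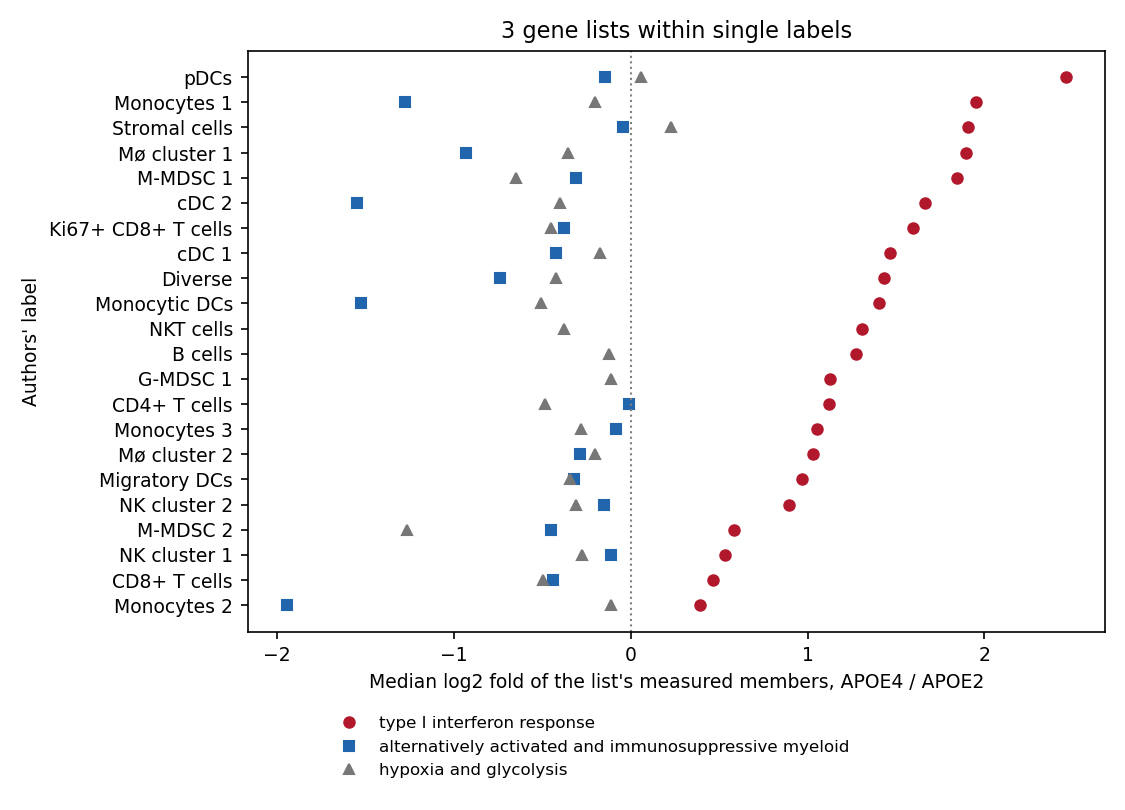
Median log2 ratio APOE4/APOE2 of 3 gene lists (type I interferon, circles; alternatively activated, squares; hypoxia and glycolysis, triangles) within single cell type names, with no mark where fewer than 5 members were measured. The type I interferon list lies above 0 in 22 of 22 names, the alternatively activated list lies below 0 in 19 of 19, and the hypoxia list lies above 0 in 2 of 22.

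Apoe was examined in every class as the engineered locus. The count uses the mouse gene model, and transcripts of the human sequence enter it only where they align, so these values do not check the genotype. Apoe was at 158 and 87.6 CPM over all cells, a ratio of 0.555 [0.532, 0.580]. It was at 291 and 190 CPM in the monocyte/macrophage class, a ratio of 0.652 [0.620, 0.685], and at 74.2 and 38.4 CPM in MDSCs, 0.517 [0.372, 0.714]. The make-up of both these classes differs between the libraries. The difference was within counting error in DCs (0.837), T cells (0.815) and NK cells (0.709). Of the remaining classes, Apoe was highest in mast cells and basophils, at 430 and 115 CPM, a ratio of 0.266 [0.164, 0.416]. It was also lower in B cells (0.279), cycling myeloid cells (0.397), cycling T cells (0.571) and the mixed cluster (0.670). In stromal cells (0.815) the difference was within counting error.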

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

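The tests of class make-up, of shares as parts of 1 whole, of Pydc3 and of free RNA behind the lower genes were chosen only after the result was seen, as was the 2-source version of the free RNA test. All 3 patterns weighed were found and tested on the same data and stand as hypotheses. APOE genotype is the biological explanation the design names. It stays open and untested throughout, since the genotype and the library cannot be told apart.

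Barcodes outside the authors' annotation carried mast cell transcripts. Placed by own clusters, 29 such barcodes in the APOE2 library and 19 in the APOE4 library fell in the mast cell and basophil clusters, 32.6% [23.02, 43.3] and 35.8% [23.1, 50.2] of those clusters. These were the highest left-out shares among the 10 own classes, and they were picked after the left-out barcodes of all 10 had been looked at. Of the UMIs of the mast cell chymase gene Cma1 in left-out barcodes, 2660 of 2665 in APOE2 and 1574 of 1574 in APOE4 lay in these clusters. Cma1 is among the fixed markers by which these clusters were named, so this does not test their identity. With all barcodes counted, mast cells and basophils had a share ratio of 0.530 [0.378, 0.743], near the 0.505 of the annotated cells.

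Both interferon lists had higher medians in the APOE4 library in each of the 5 classes, though the interval of the interferon gamma list in NK cells included 0. A different make-up of the classes as the whole cause is argued against by the single labels, since 22 of 22 had a type I interferon median above 0. Free RNA from macrophages is argued against as well, since with C1q genes as its gauge the excess in T cells was 10.7 times [7.55, 13.9] what it could bring, and in NK cells 30.2 times [24.5, 40.9], and with neutrophil genes as another source 16.0 and 15.7 times. A library batch stays open because each genotype has 1 library. More interferon in APOE4 hosts stays open too and was not tested. Over the class, Ifng was 6.55-fold higher in T cells, or 3.71-fold with equal label weight. Over all NK cells Ifng was level (1.00 [0.829, 1.21]), but it was higher in NK cluster 1 and lower in NK cluster 2.

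CD8+ T and NK labels were higher and macrophage labels lower in the APOE4 library. That macrophages are lower only because lymphocytes take more of a fixed whole is argued against by the myeloid cells alone, where the ratio of the 3 macrophage labels was 0.497 with an upper bound of 0.553. The authors' filter on barcodes is argued against as the cause of the NK gap, because the ratio over all barcodes was 2.57 with a lower bound of 2.25. A few of the 6 pooled mice could carry the difference, and cells bear no mark of their mouse, so this and the genotype cannot be told apart.

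A set of 7 genes of 8751 measured in at least 4 classes had a log2 ratio of at least 1.5 either way, in the same direction in every class measured, by a rule set after their values were seen. Cxcl9, Gm12185 and Pydc3 (83 and 1674 UMIs) were higher in APOE4, and Erdr1 (769 and 59), Gm20186 (902 and 20), Gm26740 (2776 and 0) and Mid1 (609 and 27) lower. Free RNA as the source of the 4 lower genes is argued against, since in the APOE2 library their UMIs per cell differed between the highest and the lowest class, 14.5-fold in the median, though less for Gm26740 (1.14 in T and 0.340 in NK cells) and Gm20186 (0.335 in T cells and 0.0934 in the monocyte/macrophage class). Pydc3 may be 1 more interferon gene: the lower bound of its ratio passed every member of both lists in 3 of 5 classes, but not in MDSCs (Gbp4 at 5.23 against 4.26) or T cells (Cxcl9 at 3.74 against 2.25), and an earlier written bound was wrong because Pydc3 had been picked for its size. A DNA difference between the colonies might also explain genes nearly absent from 1 library, such as Gm26740 with its 2776 and 0 UMIs, or Mid1 and Erdr1 at the pseudoautosomal boundary, and without sequence reads it and the genotype cannot be told apart.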

How the results depend on the processing

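The alternatives with equal label weight for lists, with Scrublet scores for folds, lists and depth, and with clusters built without differing genes were chosen only after seeing the data. Except where stated the cause was not tested. Of the shares of main classes, 38 values stayed within their counting interval, 12 moved and 1 reversed. The log2 ratio for T cells, 0.87, reversed to −0.15 of lymphoid cells, and was 0.64 and 0.69 with own clusters at resolutions 1 and 2 and 0.69 over all barcodes. Over all barcodes, clusters of 363 and 179 cells named T scored next on macrophage markers. At resolution 1 a cluster of 523 cells was named T. At resolution 0.5, where the T share stayed, a cluster of 520 cells went to macrophages with regulatory T cells next. Every T value from own clusters may thus include cells of the mixed cluster. Lymphoid cells went from 1.02 to 0.88 at resolution 1 and 0.90 over all barcodes. NK cells went from 1.38 to 0.36 of lymphoid cells. The monocyte/macrophage class went from −0.36 to −0.0013 of myeloid cells and −0.22 under 5% mitochondrial UMIs, DCs from −0.43 to −0.067 and −0.65, and MDSCs from −0.07 to 0.29 and −0.24. These denominators change the question by construction. The interferon lists kept their direction in all 120 values, 5 of which moved: with equal label weight type I went to 1.33 in the monocyte/macrophage class and 1.28 in MDSCs and interferon gamma to 1.46 in MDSCs, and with own clusters T cells had 0.60 for interferon gamma and 1.36 for type I.

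With at least 400 UMIs per gene, 5, 6 and 7 of 12 named genes stayed for the monocyte/macrophage, DC and T classes, since fewer genes pass. Of the named genes' folds, 332 values stayed, 50 moved and 1 reversed, Mt3 at 0.11 with own clusters. NKT cells reversed to −0.53 of lymphoid cells. CD4+ T cells (−0.87), B cells (−0.44) and cycling CD8+ T cells (−0.69) also changed sign there. Their main intervals included 1, so they were not counted as reversed. Of other list medians, 1190 stayed, 46 moved and 15 reversed. The inflammatory list reversed in T cells to 0.24 (at least 100 UMIs), 0.011 (mean of members), 0.091 (mean of cells) and 0.094 (thinned cells), and in NK cells to 0.15 (at least 100 UMIs), 0.030 (Scrublet scores), 0.039 (own clusters) and 0.35 (equal label weight). The others were MHC class II in MDSCs at 0.33 (Scrublet scores) and in NK cells at 0.24 (own clusters), lysosome in MDSCs at 0.028 (mean), naive and memory in T cells at 0.019 (own clusters), proliferation in T cells at 0.039 (thinned) and trafficking in NK cells at 0.028 (mean of cells) and 0.047 (own clusters). Removing cells that Scrublet calls was not run, as it called 0 and 3. Depth limits genes with few UMIs, and of the 5 classes MDSCs had the lowest medians per cell, 1666 and 1682 UMIs.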

Other observations

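The genes followed within single labels were chosen only after their values were seen, and the tests of the other parts are not repeated here. In NK cells, granzymes C, D and E were lower in the APOE4 library. There, Gzmc was 37.9-fold and 19.4-fold lower in NK clusters 1 and 2, Gzmd had 218 and 1 UMIs in NK cells of APOE2 and APOE4, and Gzme 116 and 3. Gzmf, with 3 and 0 UMIs, did not differ beyond counting error. Granzyme B (Gzmb) was 1.25-fold higher [1.18, 1.32] in APOE4, while perforin (Prf1, 1.15 [0.969, 1.37]) and Ifng (1.00 [0.829, 1.21]) did not differ beyond counting error over all NK cells. Ifng went opposite ways in the NK clusters, 4.08-fold higher [2.35, 7.67] in cluster 1 and at a ratio of 0.701 [0.568, 0.867] in cluster 2. In CD8+ T cells Ifng was 4.47-fold higher [3.40, 6.00] and Lag3 2.14-fold, and Pdcd1 only 1.19-fold. In the CD4+ label Ifng was 8.64-fold higher [4.01, 22.2], beside Cd8a at 5.37-fold [2.10, 17.5] and Cd8b1 at 9.26-fold [3.76, 29.5], and in NKT cells it did not differ beyond counting error (1.45 [0.803, 2.73]). In the CD4+ label Foxp3, the regulatory T cell factor, was at 430 and 276 CPM, a ratio of 0.642 [0.553, 0.745]. Clusters built without the differing genes gave regulatory T cells 4.01% and 2.92% of cells, a ratio of 0.727 [0.590, 0.896]. Il17a in the CD4+ label had a ratio of 0.809 [0.673, 0.972]. That label also holds most of a cluster of 25 and 69 cells that scored highest on gamma delta T cell markers, of which only 2 were detected. It carries CD8 transcripts too, so these ratios cannot be read as those of CD4+ T cells alone.

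Arg1 was 7.56-fold lower [6.59, 8.69] in Monocytes 1 of APOE4, and 1.92-fold and 1.57-fold lower in Mø clusters 1 and 2, so it was lower inside labels and not only through their mix. Chil3, of the same alternatively activated list, went the other way in these Mø clusters, 5.22-fold [3.01, 9.40] and 4.02-fold higher [2.39, 6.85] from at most 48 UMIs per library. In cDC2, Mgl2 was at 1319 and 231 CPM, 5.71-fold lower [5.28, 6.18], and Ccl17 7.14-fold lower, while Mgl2 in pDCs had a ratio of 0.987. Langerin (Cd207) had 149 and 0 UMIs in migratory DCs and 61 and 0 in cDC2. Il12b, which encodes an interleukin 12 subunit, was slightly lower in migratory DCs, with a ratio of 0.820 [0.771, 0.872].

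The remaining lists complete the 125 combinations, given as medians for the monocyte/macrophage, DC, MDSC, T and NK classes in that order. Oxidative phosphorylation had −0.15, 0.03, −0.15, −0.06 and −0.09. Ribosomal proteins had −0.23, −0.15, −0.35, −0.03 and −0.15, and mitochondrial genes −0.52, −0.10, −0.24, −0.16 and −0.21. Dissociation stress genes, which rise during tissue digestion, had 0.16, −0.05, −0.05, −0.06 and 0.07. The unfolded protein response had 0.20, 0.20, −0.40, 0.01 and 0.09, with Hspa5 (0.551) and Xbp1 (0.587) lower and Atf3 (1.39) higher in MDSCs. The 4 measured sex-linked genes, all on the Y chromosome, had −0.01, 0.05, −0.40, −0.12 and 0.03. Complement had −1.57 in DCs (but 2.61 in pDCs) and −2.79 in MDSCs, both with intervals that included 0. It had −0.48 in T cells and a median ratio of 0.177 in NK cells, where 3 members were measured. Lysosomal genes had −0.06, −0.20, −0.34 and −0.30 in the DC, MDSC, T and NK classes, and proliferation −0.07, −0.05, −0.33 and −0.06.

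Lists written for other cell types were read as well, in the same order. Alternatively activated genes had −0.54 in MDSCs, −0.10 in T cells and −0.24 in NK cells, and inflammatory cytokines −0.07, −0.68, −0.13, −0.21 and −0.22. Cytotoxic genes had 0.73, 0.68 and 0.16 in the monocyte/macrophage, DC and MDSC classes, with Ccl5 3.78-fold higher in the first. Exhaustion genes had 0.05, 0.22 and −0.03 there and −0.05 in NK cells, naive and memory genes 0.12, 0.61 and −0.01, and activation genes −0.41, −0.17 and 0.08, with −0.35 in NK cells. Granule contents had 0.19, −0.91, −0.21 and 0.42 in the monocyte/macrophage, DC, T and NK classes, and neutrophil trafficking 0.19, −0.01, −0.05 and −0.18.

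The mixed label held cells with transcripts of separate lineages. In 387 of its 481 cells (80.5% [76.6, 83.9]) there were at least 3 UMIs each of T cell and of myeloid genes, against 219 of 9569 (2.29%) in other labels, and its median depth was 11778 UMIs against 5988. Gsr and Gm29243, lower in MDSCs and higher in T cells, lie on chromosome 8 at 33652523 to 33698163 and 34216859 to 34226145. Pydc3 and BC094916, both higher in T cells, lie on chromosome 1 at 173673675 to 173698395 and 173519717 to 173535957. No test was run on these positions.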
